A study of Mus musculus with 12 samples.

How the data were processed

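Poly(A) RNA of mouse (C57BL/6) was sequenced in 12 libraries that the labels place in 4 groups of 3. The liver groups were untreated liver and liver 2 h after LPS, the bacterial lipopolysaccharide that activates toll-like receptor signalling. The other groups were peritoneal macrophages given a lentivirus carrying a short hairpin RNA for 72 h and then LPS for 2 h. The hairpin was either a negative control (shNC) or directed against the long non-coding RNA Gm26917 (shGm26917). Groups and replicate numbers were taken from the sample titles and treatment labels.

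The deposited values were counts, per the file headers: whole-number read counts per Ensembl gene ID, not normalized, in 1 table per library. The submitters' processing notes name STAR, featureCounts 1.6.3 and mm10. The parameters, the annotation release, the treatment of multi-mapping reads and whether strand was used are not given in the sources used here. Reads of genes that overlap, that lie antisense to each other or that have near-identical copies could therefore be split or shared. A limit of this kind is given for Gm26917, Hbb-bs, Ifit3 and Ifit3b. It may apply to other named genes, among them Ly6c2 and the Gbp family. There were 49585 gene IDs for liver and 55401 for macrophages, with 49022 shared, so the tables came from different annotations and each tissue was analysed alone. The macrophage columns carry the word combined in their headers, and what was combined is not given in the sources used here. Gm26917 was not analysed here in the macrophage libraries. No table held a line without a gene ID.

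Symbols were taken from a table of gene names, which matched 49326 liver IDs and 55141 macrophage IDs. The unmatched IDs (259 and 260) held at most 0.0184% of the counts of a library. Coordinates and gene types are those of GENCODE M21 (GRCm38, the assembly called mm10), and the position of the 18S-related sequence next to Gm26917 is that of RefSeq on the same assembly.

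Each tissue was fitted by itself in edgeR 4.0.16 under R 4.3.3, with the group as the sole factor. Genes were kept with filterByExpr at its default settings, which left 13869 genes in liver and 12876 in macrophages. Library sizes were scaled by TMM. Differences were tested with the quasi-likelihood F test (glmQLFit and glmQLFTest, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in that tissue. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are treated minus control, that is LPS minus untreated, or shGm26917 minus shNC. The standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM on the TMM-scaled library sizes, given as mean ± SD over 3 libraries.

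Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Lists with at least 5 tested members were tested, 2-sided, with Benjamini-Hochberg adjustment over the lists of 1 comparison. Camera with a correlation estimated for each list and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Members changed were counted from the edgeR test over all genes and again adjusted over the list alone. The 39 lists covered the following groups. Responses to LPS were acute phase proteins, inflammatory cytokines and chemokines, interferon-stimulated genes, NF-kB feedback regulators, immediate early genes, and endothelial adhesion and coagulation. Metabolic lists were drug-metabolising cytochrome P450 and conjugation, bile acid synthesis and transport, fatty acid oxidation and ketogenesis, gluconeogenesis and glucose handling, lipogenesis and cholesterol synthesis, glycolysis and HIF1 targets, and the circadian clock. Stress and growth lists were cell death, oxidative stress NRF2 targets, endoplasmic reticulum and integrated stress, heat shock, and cell cycle. Macrophage lists were classical and alternative activation markers, annexins and formyl peptide receptors, phagocytosis and lysosome, antigen presentation, large peritoneal macrophage markers, small peritoneal macrophage and dendritic cell markers, Kupffer cell markers, and monocyte and macrophage markers. Markers of other cell types were those of neutrophils, T and NK cells, B cells, sinusoidal endothelial cells, stellate cells with fibroblasts and mesothelium, cholangiocytes, hepatocytes, erythroid cells, and mast cells with eosinophils. Lists of RNA classes were transcripts that overlap ribosomal RNA repeats, mitochondrially encoded transcripts, and cytosolic ribosomal proteins. The first of these also held the non-coding RNAs Rmrp, Rpph1, Rn7sk and Rn7s1, which do not overlap such repeats. Some genes stand in more than 1 list, such as Tnf, Il6 and Il1b among both the cytokines and the classical activation markers.

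A further test asked how genes that moved with LPS in liver stood in the macrophage comparison. Sets were genes with an adjusted p under 0.05 and a log2 fold change of at least 2, or at most -2, in liver, and camera was run on them in the macrophage contrast. These comparisons share no library.

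Groups, tests, lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule named Gm26917, Anxa1, Tnf, Il6, Il1b, Nos2, Arg1 and Mrc1 in both comparisons. It then took the 4 largest rises and 4 largest falls among changed genes with a mean of at least 5 CPM, a named symbol and no overlap between the groups. For the 8 lists with the smallest camera p it took the 3 members with the smallest edgeR p. Genes outside this rule are given as examples and were chosen after their values were seen.

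The alternatives were RLE size factors or library totals in place of TMM, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, ribosomal and mitochondrial transcripts left out of the library sizes, all 12 libraries in 1 fit, each library left out in turn, an absolute log2 fold change of at least 1, and for lists the estimated correlation and fry. Counts of list members without untreated liver replicate 3, shNC replicate 2 or shGm26917 replicate 3, and the lists under library totals, were added after the data were seen.

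The steps were tested on simulated data drawn from the means and library sizes of the real samples with 200 genes changed by an absolute log2 of 1 or 2. The genes of 1 further list were shifted upward. Of the genes simulated for liver, 13250 passed the filter. There 88% of genes changed by an absolute log2 of 2 and 19% of those changed by 1 were recovered, and 6 of 130 calls were false (4.62%). For macrophages 12420 passed, the shares were 91% and 21%, and 11 of 137 calls were false (8.03%). The latter share is more than the adjusted p threshold of 0.05 aims at. None (0) of the 20 unshifted lists in either simulation had a camera p under 0.05. Simulated genes were drawn independently of each other, and far fewer of them changed than in the real data. The simulation therefore cannot show how many list calls would be false where genes move together. Libraries of 1 group were compared with a chi-square statistic over genes, and all pairs differed by far more than sampling noise (20.6 to 228 per gene), so none were treated as duplicates. The labels do not say whether replicates were separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Sex-linked transcripts of shGm26917 replicate 3 differed from those of the other macrophage libraries, so its cells came from another donor.

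Depth, rounded to 6 digits, was 17322800 to 20914000 counts per library in liver and 15605300 to 18062900 in macrophages. Where a group held no count of a gene, the fold is given as a bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio has a 95% exact interval. Floors and intervals cover counting error only.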

Results

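Gene expression was measured by poly(A) RNA sequencing in mouse liver and in cultured peritoneal macrophages, the resident phagocytes of the abdominal cavity. The liver libraries comprised 3 from untreated mice and 3 from mice 2 h after LPS. The macrophage libraries comprised 3 given the control hairpin (shNC) and 3 given the hairpin against Gm26917 (shGm26917), all 72 h after the lentivirus and 2 h after LPS. Depth, rounded to 6 digits, was 17322800 to 20914000 counts per liver library and 15605300 to 18062900 per macrophage library, with a count in 17303 to 20423 genes. The 10 most abundant genes took 11.4% to 21.4% of the counts of a library. Mitochondrially encoded transcripts took 5.05% to 9.61% of counts in liver and 0.522% to 0.973% in macrophages.

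The first comparison asked which genes differed in liver 2 h after LPS, the model of acute liver injury named in the series title. Chemokine and cytokine transcripts rose together in the LPS livers. Cxcl10, an interferon-induced chemokine that attracts T cells, rose from 2.44 ± 0.909 to 4053 ± 276 CPM (SD, n = 3 per group), and Tnf from 0.0907 ± 0.0928 to 28.3 ± 4.33 CPM. The acute phase protein Saa3 rose from 3.33 ± 2.69 to 2980 ± 686 CPM, and the interferon-induced GTPase Gbp5 from 1.83 ± 0.269 to 421 ± 33.4 CPM. In the opposite direction, G6pc, which releases free glucose from the liver, fell from 561 ± 335 to 3.45 ± 2.72 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 188 ± 63.0 to 7.41 ± 2.22 CPM and Pck1, a key enzyme of gluconeogenesis, from 5106 ± 963 to 399 ± 46.3 CPM, both genes chosen after their values were seen. On the log2 scale, Tnf (8.19) and Saa3 (9.81) stood at 9.09 and 10.63 without untreated replicate 2, and G6pc (-7.35) at -8.16 without LPS replicate 1.

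By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6287 of 13869 genes tested in liver changed (45.3%), with 3227 higher and 3060 lower. Of these, 4373 had an absolute log2 fold change of at least 1, 2239 of them higher and 2134 lower. The groups' values did not overlap in 57.8% of tested genes, against 10% by chance for 3 against 3. Scaling by library totals alone shifted the median log2 fold change of all genes by -0.43 and gave 1943 higher and 5305 lower genes, 26.8% higher in place of 51.3%. All changes in liver are therefore relative to the TMM scaling, whose factors were 1.07 to 1.27 in untreated and 0.845 to 0.881 in LPS libraries.

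Among the largest rises, Sele, an endothelial adhesion molecule for leukocytes, had 0 counts in the untreated libraries and was at least 495-fold higher with LPS. Ch25h, an enzyme that makes 25-hydroxycholesterol, was at least 476-fold higher by the same floor, and Nos2, the inducible nitric oxide synthase, at least 213-fold. The monocyte chemokine Ccl7 had 3 counts in untreated libraries and 4082 with LPS, a ratio of 1820 with a 95% interval of 622 to 8829. The largest falls under the rule for named genes were those of G0s2, an inhibitor of triglyceride lipolysis (189-fold lower), G6pc (163-fold lower), Clec14a, an endothelial lectin (134-fold lower, log2 fold change -7.06, and -8.33 without LPS replicate 1), and Spata2l (97.0-fold lower). Adjusted p-values from edgeR for these genes lay between 1.42e-06 for Ccl7 and 0.000178 for Ch25h.

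**Figure D1:**
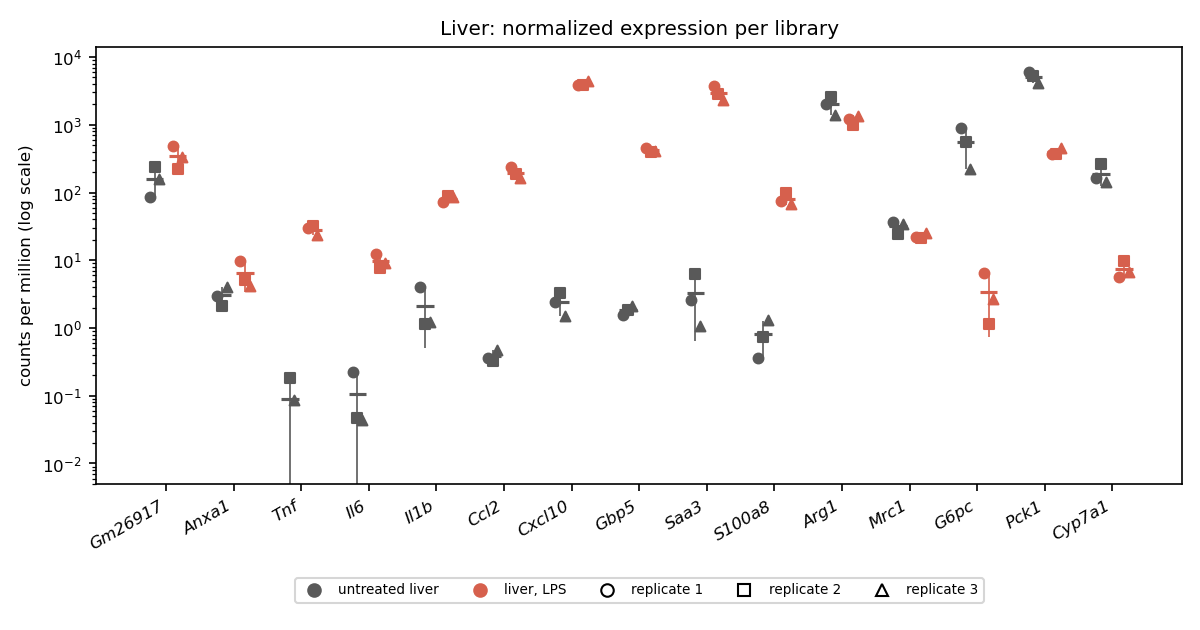
CPM of 15 genes in each liver library on a log axis, with the mean as a bar and the SD as a line that runs to the axis floor where it exceeds the mean; untreated replicate 1 holds 0 counts of Tnf and has no point. Cxcl10 stood at 2.44 CPM in untreated liver and 4053 CPM with LPS, while the groups overlapped for Gm26917 and Mrc1.

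Of the 38 lists tested in liver, 20 were called by camera, 17 higher and 3 lower, and only that of cytokines and chemokines stayed below 0.05 with an estimated correlation. All 24 tested cytokines and chemokines rose, 24 also when adjusted over the list alone, with a median log2 fold change of 6.09 (camera adjusted p = 1.80e-17, and adjusted p = 0.0229 with an estimated correlation). Ccl2, Ccl3 and Ccl4, which recruit monocytes and macrophages, rose 498-fold, 181-fold and 835-fold. Il6 rose 86.5-fold and Il1b 38.1-fold (log2 fold changes 6.44 and 5.25, and 7.55 and 6.08 without untreated replicate 1). All 29 interferon-stimulated genes rose (29 adjusted over the list alone), with a median of 5.21 (camera adjusted p = 2.93e-22, and adjusted p = 0.0857 with an estimated correlation). They included Isg20 at 37.0-fold and Cd274, which encodes the immune checkpoint ligand PD-L1, at 128-fold. Of the NF-kB feedback regulators, 21 of 22 rose (21 adjusted over the list alone) with a median of 4.27 (camera adjusted p = 1.80e-14, and adjusted p = 0.131 with an estimated correlation). Tnfaip3, a deubiquitinase that restrains NF-kB, rose 151-fold, Socs3 69.7-fold and Relb 44.0-fold.

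All 16 classical macrophage activation markers rose in liver (16 adjusted over the list alone; median 5.51, camera adjusted p = 2.70e-12, and adjusted p = 0.0857 with an estimated correlation). Cxcl9 rose 324-fold and Cd40 54.7-fold. Immediate early genes rose in 12 of 16 cases (13 adjusted over the list alone), led by Atf3 at 135-fold, Junb at 10.7-fold and Klf6 at 6.04-fold (camera adjusted p = 9.45e-06, and adjusted p = 0.379 with an estimated correlation). Acute phase proteins, plasma proteins that the liver makes in inflammation, rose in 25 of 27 cases (26 adjusted over the list alone), with a median of 2.47 (camera adjusted p = 2.19e-12, and adjusted p = 0.131 with an estimated correlation). Serpina3n rose from 483 ± 80.3 to 5186 ± 1365 CPM and Il1rn, the interleukin-1 receptor antagonist, 42.2-fold. Of the endothelial adhesion and coagulation list, 8 of 11 rose (8 adjusted over the list alone; camera adjusted p = 5.18e-05, and adjusted p = 0.171 with an estimated correlation). Procr rose 38.3-fold and the adhesion molecule Icam1 28.3-fold. The medians of the classical and endothelial lists (5.51 and 3.77) were the same with the 1 member of each that had no untreated count set at its bound.

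Neutrophil, T and NK cell and erythroid markers were called higher in LPS livers. Of 12 neutrophil markers, 11 rose (12 adjusted over the list alone), with a median of 5.59 (camera adjusted p = 2.07e-08, and adjusted p = 0.221 with an estimated correlation). S100a8 and S100a9, which encode the subunits of calprotectin, rose 99.5-fold and 87.0-fold, and Retnlg 76.9-fold. The log2 fold change of S100a9 was 6.44, and 7.36 without untreated replicate 3. T and NK cell markers rose in 5 of 13 cases (5 adjusted over the list alone), with the granzyme Gzmb, chosen after its value was seen, at 13.6-fold (camera adjusted p = 0.0286, and adjusted p = 0.490 with an estimated correlation). That list was not called without untreated replicate 3 (adjusted p = 0.0996), and 3 members rose without any 1 of untreated replicate 1, untreated replicate 3 or LPS replicate 1, and with library totals. Erythroid markers rose in 5 of 6 cases (5 adjusted over the list alone), among them the haemoglobin gene Hbb-bs, chosen after its value was seen, from 108 ± 23.4 to 411 ± 133 CPM (camera adjusted p = 0.0130, and adjusted p = 0.490 with an estimated correlation). Hbb-bs has a near-identical copy, Hbb-bt, with which it may share reads, and its edgeR adjusted p was 0.0740 with all 12 libraries in 1 fit. The monocyte and macrophage markers moved both ways, with 3 higher and 3 lower of 11 (3 and 3 adjusted over the list alone) and no call (adjusted p = 0.890). With library totals 2 were higher and 5 lower. Kupffer cell markers had 1 higher and 4 lower of 11 (1 and 4 adjusted over the list alone; adjusted p = 0.0923), and were called lower without LPS replicate 2 (0.0253). Slc40a1, the iron exporter ferroportin, was 7.13-fold lower and the scavenger receptor Marco 5.81-fold higher, both chosen after their values were seen.

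Lists of gluconeogenesis, lipogenesis and the circadian clock were called lower. Of the gluconeogenesis and glucose handling list, 7 of 12 fell (7 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 0.00803, and adjusted p = 0.197 with an estimated correlation). Pck1 was 12.8-fold and Ppargc1a, a transcriptional coactivator of gluconeogenesis, 8.26-fold lower. Of the circadian clock genes 7 of 13 fell (7 adjusted over the list alone; camera adjusted p = 0.0286, and adjusted p = 0.323 with an estimated correlation). The clock repressors Nr1d1 and Cry2, chosen after their values were seen like Ppargc1a, were 33.4-fold and 18.9-fold lower. Of lipogenesis and cholesterol synthesis, 7 of 15 fell (7 adjusted over the list alone; camera adjusted p = 0.0286, and adjusted p = 0.659 with an estimated correlation). Untreated replicate 3 stood apart in both lists: Per3 was 45.5 CPM there and 0.774 and 0.788 CPM in the other untreated libraries, Arntl 1.17 against 26.7 and 31.8, and Scd1 20854 against 1197 and 1282. Without it the lipogenesis list was not called (adjusted p = 0.252, with 5 lower and 2 higher), nor without LPS replicate 1 (0.0634), while the clock list was (0.00644, with 6 lower). Library totals alone ended both calls (0.0940 each), while the falls were larger, with 10 lower and a median of -1.94 in place of -1.53 for lipogenesis and 9 lower and a median of -1.38 in place of -0.96 for the clock. Leaving out LPS replicate 2 or 3 left 4 lower members in each list, and leaving out LPS replicate 1 left 4 in the lipogenesis list.

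Bile acid synthesis and transport had 8 lower and 1 higher of 16 members (8 and 2 adjusted over the list alone) without a call (adjusted p = 0.0821), but were called lower without untreated replicate 3 (0.0325) or LPS replicate 2 (0.0451, with 4 lower). The repressor Nr0b2, which was 20.2-fold lower, and Cyp7a1, which was 25.3-fold lower, were chosen after their values were seen. Drug-metabolising cytochrome P450 and conjugation genes had 4 lower of 24, and 7 with library totals (2 adjusted over the list alone), and no call (adjusted p = 0.118). They were called lower without untreated replicate 1 (0.0117) or LPS replicate 2 (0.0455, with 2 lower). Among sinusoidal endothelial markers, 6 of 10 were lower and 3 higher (6 and 3 adjusted over the list alone), without a call (adjusted p = 0.151). With library totals 7 were lower and 1 higher. The growth factor receptor Kdr was 7.43-fold lower and the hyaluronan receptor Lyve1 3.92-fold higher, both chosen after their values were seen.

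Among stress and death genes, 11 of 18 of the cell death list rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 8.13e-05, and adjusted p = 0.0940 with an estimated correlation). Mlkl, the effector of necroptosis, rose 15.2-fold and the inflammatory caspase Casp4 24.8-fold, while the pro-apoptotic Bbc3 was 5.76-fold lower, all chosen after their values were seen. Heat shock genes rose in 6 of 11 cases, and in 3 with library totals (8 adjusted over the list alone; camera adjusted p = 0.00435, and adjusted p = 0.323 with an estimated correlation). Endoplasmic reticulum and integrated stress genes had 7 higher and 1 lower of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0467, and adjusted p = 0.439 with an estimated correlation). Xbp1 rose 4.92-fold and Trib3 was 3.75-fold lower, both chosen after their values were seen. This call was lost without untreated replicate 1 (0.105), untreated replicate 3 (0.0598) or LPS replicate 2 (0.0699), and with a filter of 1 CPM (0.0679). Glycolysis and HIF1 targets had 8 higher and 1 lower of 14 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.323 with an estimated correlation), a call lost without untreated replicate 2 (0.0668); with library totals they had 5 higher and 2 lower. Antigen presentation had 10 higher and 1 lower of 13, and 6 and 1 with library totals (12 and 1 adjusted over the list alone; camera adjusted p = 0.000116, and adjusted p = 0.221 with an estimated correlation). The immunoproteasome subunit Psmb9, chosen after its value was seen, rose 8.25-fold.

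Cytosolic ribosomal proteins rose in 15 of 22 cases (16 adjusted over the list alone), by a median of 0.82, and in 5 cases with a median of 0.40 with library totals (camera adjusted p = 8.13e-05, and adjusted p = 0.490 with an estimated correlation). Mitochondrially encoded transcripts rose in 8 of 15 cases, and with library totals in 4 with 1 lower (8 adjusted over the list alone; camera adjusted p = 0.00229, and adjusted p = 0.490 with an estimated correlation). These took 9.61% of counts in LPS replicate 1 against 6.22% and 6.18% in the other LPS libraries, and 5 members rose without any 1 of the LPS replicates.

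The remaining lists were not called in liver. Their camera adjusted p-values were 0.0772 for cholangiocyte markers, 0.0817 for transcripts that overlap ribosomal RNA repeats, 0.0923 for annexins and formyl peptide receptors, 0.112 for alternative activation markers, 0.144 for stellate cell, fibroblast and mesothelial markers, and 0.144 for B cell markers. They were 0.159 for NRF2 targets, 0.243 for small peritoneal macrophage and dendritic cell markers, 0.508 for cell cycle, 0.533 for large peritoneal macrophage markers, 0.564 for hepatocyte markers, 0.634 for phagocytosis and lysosome, and 0.890 for fatty acid oxidation and ketogenesis. Some were called with 1 library left out: cholangiocyte markers without untreated replicate 3 (0.0235, with 4 of 6 higher in place of 1), LPS replicate 2 (0.0470) or LPS replicate 3 (0.0488), ribosomal repeat transcripts without LPS replicate 2 (0.0415), and B cell markers (0.0484) and stellate cell, fibroblast and mesothelial markers (0.0113) without LPS replicate 1. Cholangiocyte markers were also called with library totals (0.0446). Alternative activation markers had 7 higher and 1 lower of 15, and 4 and 5 with library totals. The mast cell and eosinophil list had too few tested members. The monocyte list had a median of 0.06 (-0.37 with library totals) with camera's direction down. The fatty acid oxidation list had a median of 0.19 (-0.26 with library totals) and a mean of -0.27 with camera's direction up.

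Gm26917 (ENSMUSG00000097971), the RNA targeted by the hairpin, is annotated as a lincRNA of 3329 bases on the plus strand of chromosome 17, from 39843013 to 39846341. An 18S-related ribosomal sequence, Rn18s-rs5, begins 12 bases after its end, from 39846354 to 39848202, and the lincRNAs Gm42418 and AY036118 overlap that sequence. In liver Gm26917 rose from 160 ± 74.8 to 346 ± 130 CPM (SD, n = 3 per group), a log2 fold change of 1.12 (SE 0.40, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0492). The values were 84.8, 234 and 160 CPM in untreated and 480, 220 and 338 CPM in LPS replicates 1, 2 and 3, so the groups overlapped. The call was lost without untreated replicate 1 (adjusted p = 0.109), untreated replicate 3 (0.0732), LPS replicate 1 (0.162) or LPS replicate 3 (0.0985), and with library totals alone (log2 fold change 0.73, adjusted p = 0.127). It was also lost with a filter of 1 CPM (0.0504), with the replicate number as a block (0.0890) and with ribosomal and mitochondrial transcripts left out of the library sizes (0.0509).

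**Figure D2:**
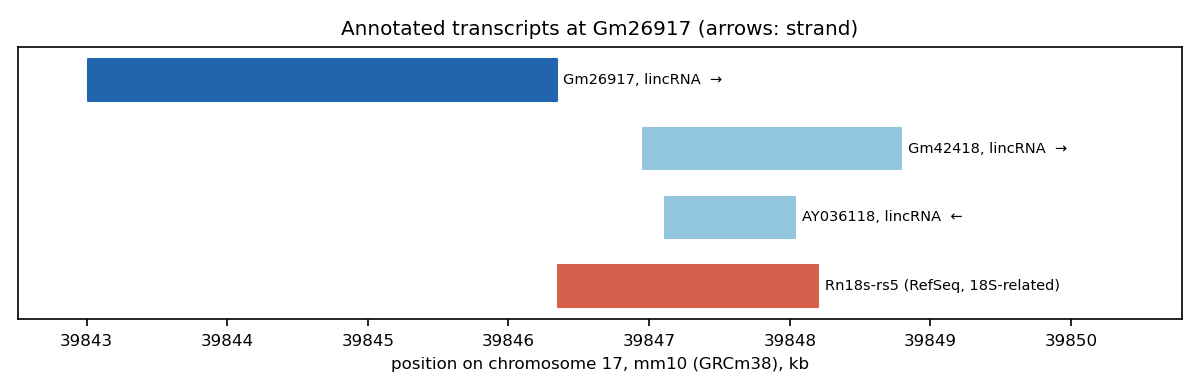
Annotated extents of Gm26917, Gm42418, AY036118 and Rn18s-rs5 on chromosome 17 (mm10, position in kb), with an arrow for the strand where the annotation used gives one. Gm26917 ends 12 bases before Rn18s-rs5, which spans 39846354 to 39848202.

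Anxa1 (ENSMUSG00000024659, chromosome 19, 20373428 to 20390944, minus strand) encodes annexin A1, the protein named in the series title and a calcium-dependent phospholipid-binding mediator of the resolution of inflammation. In liver it rose from 3.04 ± 0.932 to 6.40 ± 3.02 CPM (SD, n = 3 per group), a log2 fold change of 1.07 (SE 0.38, edgeR adjusted p = 0.0470). The call was lost without untreated replicate 1 (adjusted p = 0.103), untreated replicate 2 (0.142), LPS replicate 1 (log2 fold change 0.63, adjusted p = 0.164) or LPS replicate 2 (0.0584). It was lost with library totals alone (log2 fold change 0.64, adjusted p = 0.211), limma-voom (0.0589), the replicate number as a block (0.0581) and ribosomal and mitochondrial transcripts left out of the library sizes (0.0526). Of the annexins and formyl peptide receptors 7 were higher and 1 lower of 12 tested (7 and 1 adjusted over the list alone), and 4 and 3 with library totals. The receptor Fpr2 rose 22.1-fold and Anxa11 was 3.81-fold lower, both chosen after their values were seen. Arg1, which encodes arginase 1, stood at 2013 ± 602 and 1184 ± 195 CPM in untreated and LPS liver (edgeR adjusted p = 0.0640, 0.0168 with DESeq2 and 0.0162 without untreated replicate 3). The mannose receptor Mrc1 stood at 31.9 ± 6.28 and 22.9 ± 2.18 CPM (edgeR adjusted p = 0.0774, and 0.0243 without untreated replicate 2). Library totals alone gave adjusted p-values of 0.00727 for Arg1 and 0.00987 for Mrc1.

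The second comparison asked which genes differed in LPS-treated macrophages given the hairpin against Gm26917. Gm26917 was not analysed here in these libraries, so the knockdown behind this comparison was not checked. Transcripts of the response to LPS were lower in the shGm26917 libraries. The chemokine Ccl4 fell from 1173 ± 275 to 38.2 ± 13.4 CPM (SD, n = 3 per group), and the interferon-induced gene Oasl1, a 2'-5' oligoadenylate synthetase-like protein, from 572 ± 331 to 3.56 ± 1.30 CPM. Il6 fell from 1918 ± 1722 to 23.1 ± 9.09 CPM (log2 fold change -6.37, and -5.47 without shNC replicate 3) and Tnfaip3 from 1075 ± 189 to 168 ± 29.9 CPM. Anxa1 rose from 32.7 ± 9.32 to 115 ± 19.3 CPM, and the lysosomal acid lipase Lipa from 286 ± 21.3 to 883 ± 258 CPM.

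By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3049 of 12876 genes tested in macrophages changed (23.7%), with 1618 higher and 1431 lower. Of these, 1638 had an absolute log2 fold change of at least 1, 868 of them higher and 770 lower. The groups' values did not overlap in 45.9% of genes, against 10% by chance. The count was 5236 without shNC replicate 2, 1679 without shNC replicate 3, 1341 without shGm26917 replicate 1, 839 without shGm26917 replicate 2 and 978 without shGm26917 replicate 3. Library totals alone shifted the median of all genes by 0.29 and gave 3135 higher and 794 lower genes, 79.8% higher in place of 53.1%. shNC replicate 2 stood apart from the other control libraries, with 2155 CPM of Cxcl10 against 70.1 and 247, and 273 CPM of Il6 against 1774 and 3707. shGm26917 replicate 3 held 1 count of Xist, which the other macrophage libraries held at 3769 to 5985 counts.

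Of the 30 lists tested in macrophages, 11 were called by camera, 2 higher and 9 lower, and none (0) with an estimated correlation. All 29 interferon-stimulated genes fell (29 adjusted over the list alone), with a median log2 fold change of -4.17 (camera adjusted p = 4.26e-14, and adjusted p = 0.509 with an estimated correlation). The ubiquitin-like Isg15 was 65.6-fold, Oasl1 160-fold and the RNA sensor Ifih1 8.39-fold lower. The count was 13, 8 and 9 without shGm26917 replicates 1, 2 and 3, and the median -3.03 without shNC replicate 2. Of the cytokines and chemokines, 24 of 25 fell (24 adjusted over the list alone), with a median of -4.19 (camera adjusted p = 4.25e-13, and adjusted p = 0.309 with an estimated correlation). Ccl2 was 63.8-fold, Ccl4 30.7-fold and the granulocyte growth factor Csf3 76.3-fold lower. Their log2 fold changes moved with single control libraries, from -6.00 to -5.12 for Ccl2 without shNC replicate 2 and from -6.25 to -5.62 for Csf3 without shNC replicate 3. The count was 13 without shGm26917 replicate 2 and 14 without replicate 3. Il10, an anti-inflammatory cytokine in the same list and chosen after its value was seen, was also 13.5-fold lower (edgeR adjusted p = 0.0122, and 0.0533 without shGm26917 replicate 3; log2 fold change -3.76, and -3.01 without shNC replicate 2).

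Of the NF-kB feedback regulators, 16 of 22 fell (17 adjusted over the list alone), with a median of -1.56 (camera adjusted p = 7.90e-10, and adjusted p = 0.309 with an estimated correlation). Nfkbiz, a nuclear regulator of secondary response genes, was 9.59-fold lower (log2 fold change -3.26, SE 0.14, edgeR adjusted p = 0.00140), Zc3h12a, an endoribonuclease for cytokine mRNA, 6.64-fold and Tnfaip3 6.41-fold. The count was 10 without shGm26917 replicate 2. Of the classical activation markers, 11 of 15 fell (11 adjusted over the list alone, with 1 higher; camera adjusted p = 6.34e-05, and adjusted p = 0.309 with an estimated correlation). The costimulatory receptor Cd40 fell from 108 ± 24.5 to 10.8 ± 1.12 CPM, and Il6 was 82.8-fold (log2 fold change -6.37, and -5.47 without shNC replicate 3) and Socs3 4.53-fold lower. Without shGm26917 replicates 2 and 3 the counts were 4 and 5.

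The falls of Nos2 (log2 fold change -8.45), Cxcl10 (-9.99), Ifit3 (-9.17) and Ifit3b (-9.07) were the largest in macrophages under the rule for named genes. Part of their size depended on shNC replicate 2, without which they were -6.38, -7.64, -5.63 and -5.08 and still called, while Cxcl10 was -10.99 and Ifit3 -9.79 without shGm26917 replicate 3 and Ifit3b -8.47 without shGm26917 replicate 1. Ifit3 and Ifit3b are near-identical copies and may share reads. Their control levels varied widely, at 210 ± 278 CPM for Nos2, 824 ± 1156 for Cxcl10 and 592 ± 940 for Ifit3. The edgeR adjusted p-values were 0.00979, 0.0106, 0.0198 and 0.0319. They were 0.0817, 0.0550, 0.142 and 0.291 with limma-voom. Without shGm26917 replicate 2 they were 0.0546, 0.0575, 0.0909 and 0.114. Without replicate 3 the values were 0.0541 for Nos2, 0.0788 for Ifit3 and 0.111 for Ifit3b, and without replicate 1 they were 0.0793 for Ifit3 and 0.106 for Ifit3b. Il1b fell by 3.81 on the log2 scale (edgeR adjusted p = 0.0114), a call lost without shGm26917 replicate 2 (0.0543) or 3 (0.0622). Tnf was 3.95-fold lower, from 255 ± 91.5 to 64.5 ± 18.5 CPM (edgeR adjusted p = 0.0110, and 0.0513 without shGm26917 replicate 2).

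**Figure D3:**
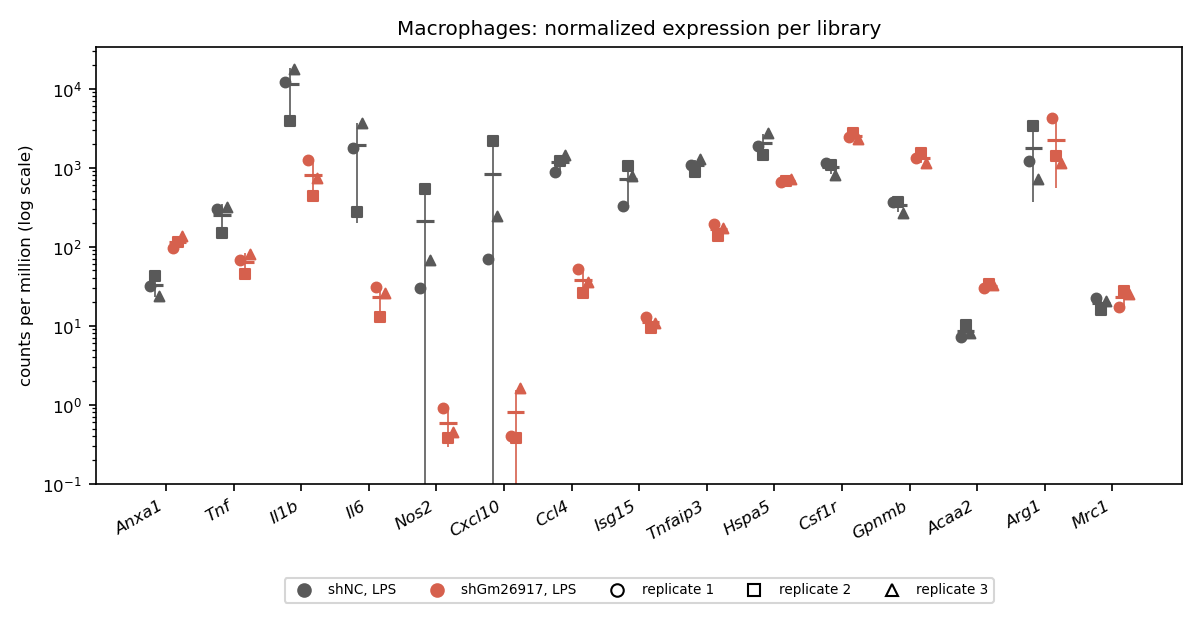
CPM of 15 genes in each macrophage library on a log axis, with the mean as a bar and the SD as a line that runs to the axis floor where it exceeds the mean. Cxcl10 spread from 70.1 to 2155 CPM over the shNC libraries, while Anxa1 stood at 32.7 ± 9.32 CPM with shNC and 115 ± 19.3 CPM with shGm26917.

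Endoplasmic reticulum and integrated stress genes fell in 7 of 12 cases with a median of -0.82, and in 4 with a median of -0.52 with library totals (7 adjusted over the list alone; camera adjusted p = 0.00361, and adjusted p = 0.509 with an estimated correlation). The chaperone Hspa5 fell from 2019 ± 671 to 683 ± 30.3 CPM and Dnajb9 was 3.72-fold lower. Between 1 and 2 members of this list fell without any 1 library other than shNC replicate 2. Hspa5 had edgeR adjusted p-values of 0.0544 and 0.0510 without shGm26917 replicates 2 and 3. Chac1, which was 4.01-fold lower, had 0.0533 to 0.0916 without any 1 library other than shNC replicate 2, and 0.0723 with all 12 libraries in 1 fit. Immediate early genes had 7 lower and 1 higher of 17, and 6 and 3 with library totals (10 and 3 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.509 with an estimated correlation). Acute phase genes fell in 4 of 12 cases (5 adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.509 with an estimated correlation). Both calls were lost without shNC replicate 2 (0.152 and 0.0703). The immediate early genes had 3 lower members without shNC replicate 3, and 3, 1 and 2 without shGm26917 replicates 1, 2 and 3, where the acute phase genes had 2, 1 and 1. The nuclear receptor Nr4a1 was 2.71-fold lower and the transcription factor Egr2 3.06-fold higher, both chosen after their values were seen (edgeR adjusted p = 0.00789 and 0.0121, with 0.234 for Nr4a1 with all 12 libraries in 1 fit and 0.0536 for Egr2 without shGm26917 replicate 3).

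Of the cell death list 5 of 18 fell (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0295, and adjusted p = 0.509 with an estimated correlation). Its median of -0.24 became 0.05 with library totals, and the call was lost without shNC replicate 2 (0.161) or shGm26917 replicate 1 (0.0535). Without shGm26917 replicate 1 or 3 it had 3 lower members. Nlrp3, a sensor of the inflammasome, was 6.88-fold and the caspase-8 regulator Cflar 2.65-fold lower, both chosen after their values were seen. Antigen presentation genes fell in 3 of 13 cases, and in 1 with library totals (3 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.539 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 were 4.35-fold and 2.09-fold lower and the class II gene H2-Ab1 1.98-fold. The log2 fold change of Tap1 was -2.12, and -1.50 without shNC replicate 2. None (0) of the 3 passed without shNC replicate 3 (edgeR adjusted p = 0.0560, 0.0766 and 0.0877) or any 1 shGm26917 library (0.0743 to 0.117). H2-Ab1 did not pass without shNC replicate 1 (0.0796) or with the replicate number as a block (0.0515). The list was not called without shNC replicate 2 (0.161) or shGm26917 replicate 1 (0.0644).

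Phagocytosis and lysosome genes rose in 7 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 0.00109, and adjusted p = 0.408 with an estimated correlation). Gas6, a bridging ligand for the uptake of dying cells, rose 8.94-fold, Gpnmb 4.01-fold from 333 ± 59.7 to 1333 ± 189 CPM, and Lipa 3.08-fold. The lipid receptor Trem2, chosen after its value was seen, rose 5.24-fold (edgeR adjusted p = 0.0115, and 0.0510 and 0.0509 without shGm26917 replicates 2 and 3). The number that rose was 14 without shNC replicate 2, 4 without shNC replicate 1 or shGm26917 replicate 2, and 3 without shGm26917 replicate 3. Fatty acid oxidation and ketogenesis genes rose in 4 of 11 cases, and in 7 with library totals (5 adjusted over the list alone; camera adjusted p = 0.0200, and adjusted p = 0.309 with an estimated correlation). Acaa2 and Acadm, enzymes of beta-oxidation, rose 3.77-fold and 1.93-fold (edgeR adjusted p = 0.00235 and 0.00868).

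The largest rises in macrophages under the rule for named genes were those of Atp6v0d2, a subunit of the vacuolar proton pump (58.1-fold), the dendritic cell receptor Clec9a (40.8-fold), Mcf2l (38.2-fold) and Tns1 (27.9-fold). Their edgeR adjusted p-values were 0.00258 to 0.00508. The log2 fold changes of Clec9a (5.35), Mcf2l (5.26) and Tns1 (4.80) moved with single libraries, Clec9a to 6.08 and Mcf2l to 6.90 without shNC replicate 1, and Clec9a to 4.76 and Tns1 to 5.39 without shNC replicate 2. The growth factor receptor Csf1r rose from 1005 ± 180 to 2502 ± 232 CPM (edgeR adjusted p = 0.00782) and the monocyte marker Ly6c2 was 11.9-fold lower (edgeR adjusted p = 0.00204), both chosen after their values were seen. Both belong to the monocyte and macrophage markers, of which 4 were higher and 1 lower of 10 (4 and 1 adjusted over the list alone; camera adjusted p = 0.184). The higher members numbered 7 without shNC replicate 2, 2 without shNC replicate 3 or shGm26917 replicate 1, and 1 without any 1 of the other libraries.

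Anxa1 was 3.52-fold higher in the shGm26917 libraries (log2 fold change 1.82, SE 0.24, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00521), and the groups did not overlap. Among the annexins and formyl peptide receptors, 3 were higher and 3 lower of 12 (3 and 5 adjusted over the list alone; camera adjusted p = 0.724). The counts were 4 and 1 with library totals, 4 and 5 without shNC replicate 2, and 3 and 1 without any 1 of the other libraries. Anxa3 rose 3.40-fold while the receptor Fpr1 was 3.83-fold lower, both chosen after their values were seen. Arg1 stood at 1752 ± 1384 CPM with shNC and 2264 ± 1719 CPM with shGm26917 (edgeR adjusted p = 0.730). Its log2 fold change of 0.37 had the opposite sign without shNC replicate 3 (-0.02) or shGm26917 replicate 1 (-0.46), and was 1.22 without shNC replicate 2. Mrc1 stood at 19.4 ± 3.45 and 23.4 ± 5.55 CPM (edgeR adjusted p = 0.424). Alternative activation markers had 1 higher and 2 lower of 18 (1 and 2 adjusted over the list alone) and were not called (camera adjusted p = 0.724), with a median of 0.21, a mean of -0.03 and camera's direction up. They had 5 higher and 2 lower with library totals, and 6 and 5 of 19 without shNC replicate 2. Without any 1 of the other libraries at most 1 was higher and at most 1 lower.

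**Figure D4:**
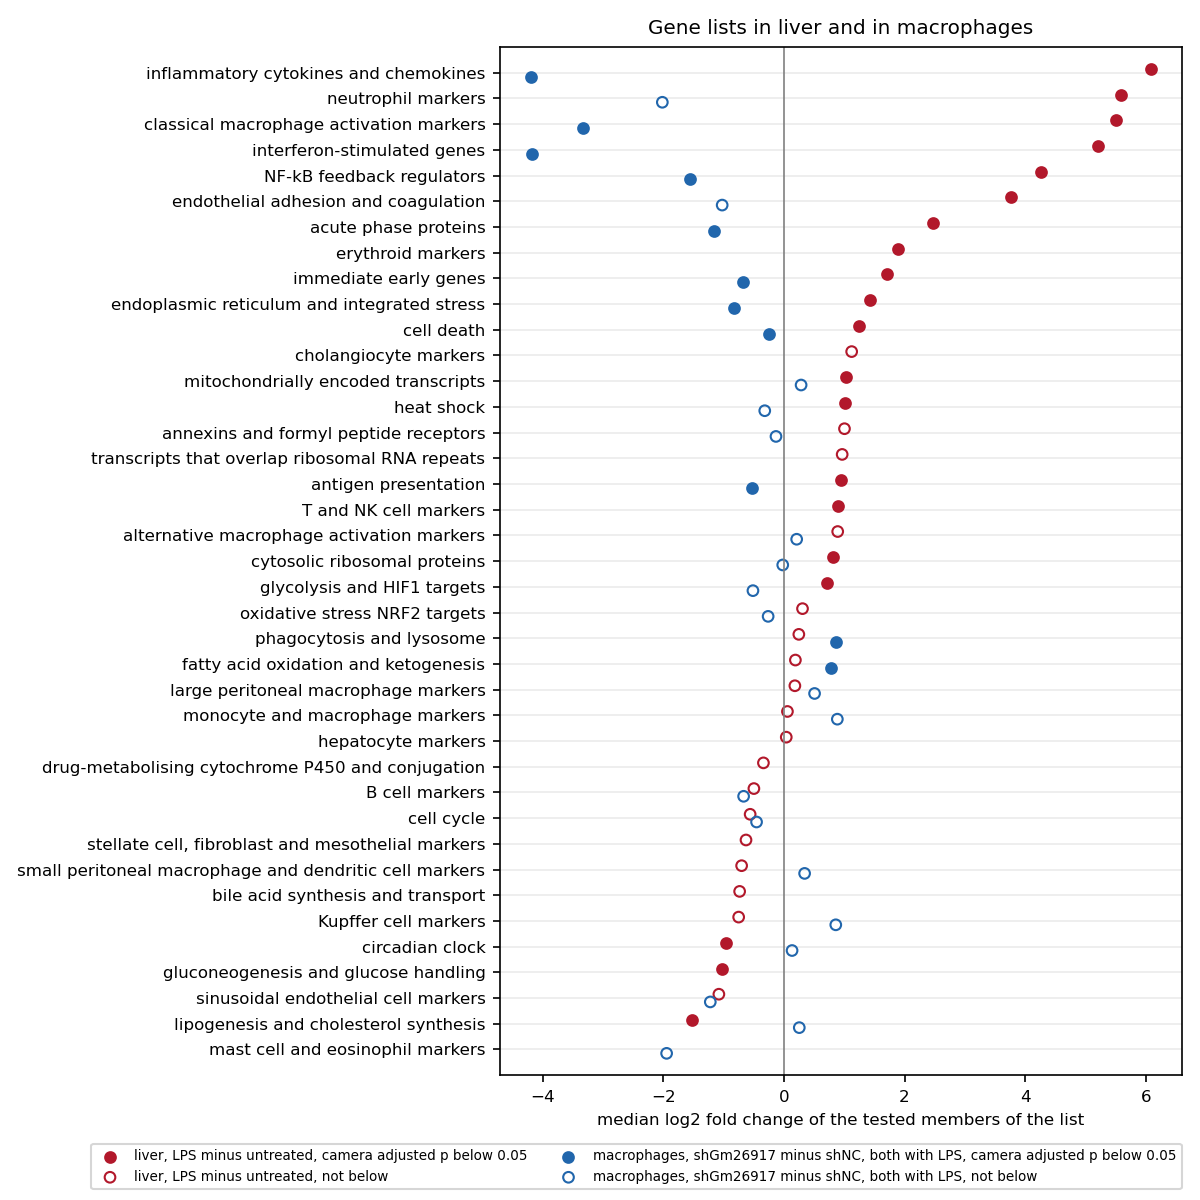
Median log2 fold change of the tested members of each list (horizontal axis) in liver, LPS minus untreated, and in macrophages, shGm26917 minus shNC, with filled points for a camera adjusted p under 0.05. Interferon-stimulated genes stood at 5.21 in liver and -4.17 in macrophages. Some medians near 0 changed sign with library totals, among them cell death (-0.24 to 0.05) and NRF2 targets (-0.26 to 0.03) in macrophages. In liver they included NRF2 targets (0.31 to -0.11), phagocytosis and lysosome (0.25 to -0.17), large peritoneal macrophage markers (0.18 to -0.24) and hepatocyte markers (0.04 to -0.37).

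The other lists were not called in macrophages. Camera adjusted p-values were 0.0759 for lipogenesis and cholesterol synthesis, 0.0800 for glycolysis and HIF1 targets, 0.126 for neutrophil markers, 0.261 for heat shock and 0.261 for Kupffer cell markers. They were 0.361 for large peritoneal macrophage markers, 0.373 for the circadian clock, 0.391 for endothelial adhesion and coagulation, 0.426 for mast cell and eosinophil markers, 0.492 for NRF2 targets and 0.492 for cell cycle. They were 0.504 for small peritoneal macrophage and dendritic cell markers, 0.504 for B cell markers, 0.635 for sinusoidal endothelial markers, 0.724 for mitochondrially encoded transcripts and 0.928 for cytosolic ribosomal proteins. Some were called with 1 library left out: lipogenesis without shNC replicate 1 (0.0425), shNC replicate 3 (0.0108) or shGm26917 replicate 3 (0.0483), glycolysis without shNC replicate 3 (0.0262), and NRF2 targets without shNC replicate 2 (0.0302). With library totals, glycolysis (0.0335), neutrophil markers (0.0161) and endothelial adhesion and coagulation (0.0401) were called. Too few members of 9 lists were expressed for a test, namely bile acid synthesis, cholangiocyte, cytochrome P450, erythroid, gluconeogenesis, hepatocyte, stellate and mesothelial, T and NK cell, and ribosomal RNA repeat transcripts. The ribosomal protein list had a median of -0.02 (0.27 with library totals) and a mean of 0.01, and the annexin list a median of -0.13 (0.16 with library totals) and a mean of 0.01, both with camera's direction down.

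A last test asked how genes that moved with LPS in liver stood in the macrophage comparison. Of 1088 genes with a log2 fold change of at least 2 in liver, 802 were tested in macrophages, where 347 were lower and 21 higher with shGm26917. Their mean log2 fold change was -1.34, and 79.4% lay below 0, against 50.1% of the 11400 genes tested in both tissues (camera p = 8.66e-18, and p = 0.0342 with an estimated correlation). Without shGm26917 replicates 1, 2 and 3 the lower members numbered 187, 134 and 136, and without shNC replicate 2 the higher members numbered 75. Of 713 genes with a log2 fold change of at most -2 in liver, 437 were tested, and 103 were higher and 22 lower, with a mean of 0.50 (camera p = 4.97e-07, and p = 0.202 with an estimated correlation). Without shNC replicate 2 the higher members numbered 185, and without shGm26917 replicates 1, 2 and 3 they numbered 42, 28 and 33. Liver at 2 h and cultured macrophages differ in cell types and in treatment, and the labels give no macrophage group without LPS.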

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

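The list members without doubted libraries and the lists under library totals were tests chosen only after the data were seen, and the other alternatives were planned. In liver the count of changed genes stayed within 1.5 times of 6287 under all alternatives (4865 to 6227 with 1 library left out, 4373 at an absolute log2 fold change of at least 1). In macrophages 3049 became 1638 at that threshold and 839 to 5236 with 1 library left out, the range ends being without shGm26917 replicate 2 and without shNC replicate 2. Without shGm26917 replicate 2, 828 of the 3049 calls (27.2%) were kept with the same sign, and without shNC replicate 2, 3014 were. Fewer libraries per group lower the power, which is part of the cause by construction. The rest of the cause was not tested.

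Gm26917 in liver (1.12) was 0.73 with library totals, 1.12 with 1 CPM in 3 libraries, 1.16 with the replicate block, 1.10 with ribosomal and mitochondrial transcripts left out of library sizes, and 0.81 to 1.47 with 1 library left out. Anxa1 in liver (1.07) was 0.64 with library totals, 1.00 with limma-voom, 1.02 with the replicate block, 1.05 with ribosomal and mitochondrial transcripts left out, and 0.63 to 1.31 with 1 library left out. Apart from the left-out libraries, the settings named for each gene are those in which its call was lost. Gm26917 kept its call with RLE size factors, no filter beyond 1 count, DESeq2 and limma-voom. Anxa1 kept its call with RLE size factors, no filter beyond 1 count, 1 CPM in 3 libraries, DESeq2 and all 12 libraries in 1 fit. Over all alternatives run, adjusted p-values were 0.0103 to 0.162 for Gm26917 and 0.0181 to 0.211 for Anxa1 in liver. Of the left-out libraries, Gm26917 kept its call without untreated replicate 2 or LPS replicate 2, and Anxa1 without untreated replicate 3 or LPS replicate 3. The cause was not tested. Anxa1 in macrophages passed under every alternative run (1.62 to 2.03 with 1 library left out). Called lists numbered 20 in liver and 11 in macrophages, and 1 and 0 with an estimated correlation. They numbered 19 to 24 and 8 to 13 with 1 library left out, and 25 and 12 with fry, which ended the calls of lipogenesis in liver (0.260) and of immediate early genes (0.0573) and antigen presentation (0.145) in macrophages. The mean of the genes lower in liver (0.50) kept its value with an estimated correlation but not its call, and was 0.37 to 0.72 with 1 library left out. The mean of the higher set kept its call in the settings run for it, namely RLE, 1 CPM in 3 libraries, the replicate block, the estimated correlation, each macrophage library left out and the lower fold threshold, and was -0.74 at an absolute log2 fold change of at least 1 in liver. Arg1 in macrophages (0.37) was -0.02 without shNC replicate 3 and -0.46 without shGm26917 replicate 1, within -0.46 to 1.22 over the left-out libraries.

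Apart from Gm26917 and Anxa1, 58 of 63 liver genes and 31 of 55 macrophage genes examined singly kept their side of the threshold and their direction under all alternatives run. Members changed in any list numbered 309 in liver and 312 without untreated replicate 3, and in macrophages 166, 236 without shNC replicate 2 and 70 without shGm26917 replicate 3. With replicate numbers as a block, 5754 liver and 2594 macrophage genes changed. Deviations of equal numbers correlated at 0.118, 0.0498 and -0.0766 in liver and at -0.0407, 0.240 and 0.178 in macrophages. Unequal numbers were not compared, so these values cannot show whether samples with the same number were paired. Gm26917 in macrophages was not run, and all 12 libraries in 1 fit gave no value for it. At 15605300 to 20914000 counts per library, genes with 0 counts in a group have only a bound.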

Other observations

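The gene families, the sex-linked genes and, for the patterns weighed, the tests of library size, macrophage share, shNC replicate 2 and ribosomal RNA precursor reads were chosen only after the result was seen, while the test of weaker LPS stimulation, those of untreated liver replicate 3 and the splits were written before. Families are tested genes whose symbols share a stem, with at least 8 members. Camera called 30 of 224 families in liver and 10 of 209 in macrophages, and 0 in either with an estimated correlation. In liver 2 h after LPS, 9 of 10 tested genes of the Psmb family and 7 of 8 of the Psma family, subunits of the core proteasome, rose (edgeR; camera adjusted p = 0.00345 and 0.0300, and adjusted p = 0.790 for both with an estimated correlation). Mitochondrial ribosomal protein genes (Mrpl) rose in 20 of 48 cases and complex I subunits of the Ndufa family in 10 of 14, with 1 lower (adjusted p = 0.00396 and 0.0356, and 0.796 for both with an estimated correlation). With library totals the medians went from 0.97 to 0.56 for Psmb, 1.02 to 0.61 for Psma, 0.51 to 0.09 for Mrpl and 0.80 to 0.39 for Ndufa. The guanylate-binding proteins (Gbp) rose in 10 of 11 cases, with a median log2 fold change of 6.62. In the other direction, 124 of 311 zinc finger genes (Zfp) were lower and 36 higher, 15 of 22 Klhl genes lower and 1 higher, and 13 of 21 kinesins (Kif) lower (adjusted p = 0.000290, 0.000627 and 0.0189, and 0.790 for each with an estimated correlation). Eif genes had 21 higher and 5 lower of 52, and their median turned from 0.37 to -0.07 with library totals.

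In macrophages with the hairpin against Gm26917, 7 of 14 regulatory proteasome subunits (Psmd) and 10 of 24 Sec genes, many of them in secretory transport, were lower, the latter with 2 higher (camera adjusted p = 0.00397 and 0.0415, and 0.879 for both with an estimated correlation). Ndufb genes of complex I rose in 7 of 11 cases and Nudt hydrolases in 6 of 19 (adjusted p = 0.0415 and 0.0457, and 0.879 for both with an estimated correlation). With library totals the medians went from -0.50 to -0.21 for Psmd and from -0.43 to -0.14 for Sec. Med genes had 5 lower of 29, and their median turned from -0.24 to 0.05 with library totals. shGm26917 replicate 3 held 1 count of Xist and 103 counts of Ddx3y, 97 of Eif2s3y, 39 of Kdm5d and 34 of Uty, while the other 5 macrophage libraries held 3769 to 5985 counts of Xist and 0 of the 4 Y-linked genes. These counts are those of male cells in replicate 3 and of female cells in the others. The shGm26917 group therefore mixed the sexes while the shNC group did not. Without replicate 3 the medians were -4.12 for the interferon list and -4.26 for the cytokine list, and Anxa1 stood at 1.69. The size of these differences therefore did not rest on the male library. Only 978 genes were called there, in place of 3049, with fewer libraries, and no other test of the mixture was made.

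LPS-response genes were low in all 3 libraries labelled shGm26917. Library totals in place of TMM shifted all genes by a median of only 0.29, so the interferon list could not move far and kept a median of -3.86. The choice between these scalings is thus too small a cause. Tests argue against a lower share of macrophages (the marker list had a median of 0.89) and against shNC replicate 2 alone (the cytokine list stood at -4.60 without it). That library did set part of the size for the interferon list. Its median was -3.03 without shNC replicate 2, in place of -4.17, with all 29 members still lower. Weaker or absent LPS stimulation in these cultures remains open, since 79.4% of the genes higher with LPS in liver lay below 0 and no macrophage group without LPS was labelled. An effect of the hairpin on the LPS response may give the same values, and the design cannot tell it apart from weaker stimulation. Neither the level of Gm26917 nor another hairpin was analysed here.

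Clock and lipid genes stood apart in untreated liver replicate 3. Genes higher with LPS had a median log2 ratio of 0.0123 in that library to the other untreated libraries. These genes were chosen in a fit that used that library as a control. Genes raised in it could have dropped out of the set, so the test cannot exclude a mixture with an LPS library. Collection at another time of day may contribute: Tef, Hlf, Nr1d2 and Per2 exceeded Clock, Nfil3 and Cry1 by 3.35 in mean log2 ratio. The former ran from 1.53 for Hlf to 3.05 for Per2, and the latter from -1.53 for Clock to -0.40 for Cry1. Clock genes are part of the pattern itself, so this gap adds little to it. Another feeding state may contribute as well, since 7 lipogenic and glycolytic genes exceeded 6 fasting genes by 3.18, and Thrsp stood at 509 CPM against 4.64 and 9.18. Most of that gap came from the lipogenic and glycolytic genes (mean 2.32), and lipid genes are part of the pattern itself. The fasting genes (mean -0.86) moved both ways, from -2.71 for Cyp4a14 to 0.87 for Pdk4. The labels give neither time nor feeding, clock and feeding genes move together, and no other biological explanation was tested.

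Gm26917 reads in liver could include ribosomal RNA precursor reads, because the annotated gene ends 12 bases before an 18S-related sequence. That test rests on annotated positions alone, and the reads were not analysed here. Gm42418 and AY036118, which overlap that sequence, held 0 counts in all 6 liver libraries, but reads that map to several places may have been left out, so this excludes little. The list of ribosomal repeat transcripts, which includes Gm26917, had 3 of 5 higher with a median of 0.97, and 0 higher with library totals. Its tested members also include Rpph1 and Rn7sk, which do not overlap ribosomal RNA repeats, so the list says little about precursor reads. A change of the transcript itself remains open.

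With 10 splits of 6 libraries the share of splits as large as the real one is never under 0.1. Each other split mixes both real groups on each side. A real difference then adds to the spread, so few called genes are likely by construction. In liver 1 of 10 splits, the real one, gave as many changed genes (6287, highest other 0), and 4 of 10 gave as many called lists (20, highest other 22). In macrophages 1 of 10 gave as many genes (3049, highest other 0) and 5 of 10 as many lists (11, highest other 13). The number of called lists thus did not set the real split apart in either tissue. The mean of the liver-higher set was as far from 0 in 1 of 10 (-1.34, highest other 0.75).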
